A study of Homo sapiens with 9 samples.

How the data were processed

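Total RNA came from SW480, a human colorectal carcinoma cell line carrying EGFP, and from lines SCP51 and SCP58, each grown from a single cell of it. It was labelled with biotin by in vitro transcription, per the labels' protocols, and hybridised to Affymetrix arrays, whose deposited tables hold 54675 probe sets. The labels name 3 biological replicates in each of the 3 groups, which makes 9 arrays, and do not say how far back the replicate cultures were separate, so p-values measure the spread between these arrays. The deposited value for each probe set is an intensity on a linear scale, made by the authors with GCOS 1.4, per the submitters' processing notes. The scaling target, the background method and the way probes were summarised are not given in the sources used here. Array medians lay between 41.1 and 44.3 and array maxima between 11162 and 12373, a range that log2 values cannot have. No detection calls were used here.

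From the deposited intensities, values below 1 (514 of them, 3 at 0) were set to 1 and log2 was taken, with no further scaling. The 62 control probe sets were left out of all tests. Probe sets were kept when they lay above the median of their array on at least 3 of the 9 arrays, which left 29166. In the annotation, 41091 probe sets carried 1 gene symbol, 1801 several and 11721 none. Symbols were brought up to date through Entrez identifiers in a RefSeq table of assembly GRCh38.p14, in which 99.9% of them matched. No genome build is named for the arrays, so no coordinates are given, and that table served only for names, for the chromosome of a gene and for the order of neighbouring genes. For each gene, the probe set with the highest mean log2 value over all 9 arrays was taken among those with 1 symbol, which gave 13598 genes. The precision is limited by the number of arrays.

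Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 9 arrays, so that the groups shared 1 estimate of the spread, with moderated variances that follow an intensity trend. The 3 comparisons were SCP51 with SCP58, SCP51 with the parent and SCP58 with the parent. A gene was called when its two-sided p, adjusted by the Benjamini-Hochberg method over all genes tested, was under 0.05. Each adjusted p printed for a gene comes from this limma test. The 44 gene lists held 849 symbols, of which 605 were tested, and were shifted in a comparison when camera (limma, preset correlation of 0.01, adjusted over the lists) gave an adjusted p under 0.05. The 42 lists with at least 5 measured genes were tested. On simulated arrays with the means and spreads of these genes, 10 runs with 200 changed genes recovered 66.6% of changes of 1 log2 unit and 93.3% of changes of 2 log2 units for SCP51 against the parent, and 4.71% of the calls were false. For SCP51 against SCP58 these were 65.9% and 94.1%, and 5.72% of the calls were false, above the limit of 5%. The simulated genes were independent, with the same spread on all 9 arrays. Among the real arrays SCP51 replicate 1 scattered more than the others, so these rates need not hold for the data.

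The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. For each comparison the rule takes, among called genes for which every array of one group lay above every array of the other, the 8 largest rises and the 8 largest falls, leaving out provisional symbols, Y-linked genes and XIST. The rule adds up to 4 called members with the smallest p of each list that was shifted or held at least 3 called genes, and up to 2 of the brightest members of a list described without a call. Genes outside the rule are said to have been chosen after their values were seen, and some genes the rule takes are left out.

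The alternatives for the values were no filter or a filter at the 65th percentile, quantile normalization or centring on the 75th percentile, and 32 added before log2. Those for the model were no intensity trend, array weights, the mean of a gene's probe sets or every probe set by itself, only the 6 arrays compared, the replicate number as a block, a 2-fold limit, an adjusted p under 0.01, each array left out in turn, and camera with an estimated correlation. An alternative added after seeing the data left the genes of chromosome 8 out of the lists. Figures were drawn with matplotlib 3.10.9.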

Results

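Gene expression was profiled in 3 groups of cultured human cells with 3 arrays each. The parent was the SW480 colorectal carcinoma line expressing EGFP, and the other groups, SCP51 and SCP58, were lines each grown from a single cell of it. After implantation into the organ of origin in mice, SCP51 was classed as highly and SCP58 as poorly metastatic. The question was which genes distinguish these lines from each other and from the population they came from. Each metastatic class was represented by 1 line, so every difference given here is between lines.

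Array medians ranged from a signal of 41.1 to 44.3. One array, SCP51 replicate 1, stood apart. Its correlations with the others across genes were 0.891 to 0.911, against 0.945 to 0.979 among the other 8 arrays (28 pairs; genes are not independent replicates). Its trimmed mean signal was 124, against 141 to 149 on the others. The median SD of a gene within the SCP51 group was 0.21 log2 units, or 0.13 without that array, against 0.13 in the parent and 0.17 in SCP58.

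**Figure D1:**
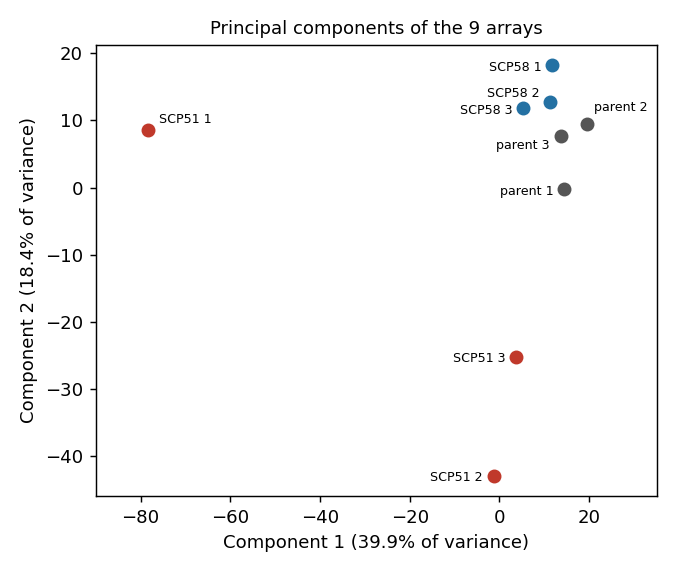
Principal components of the log2 values of the 13598 tested genes, with 1 point per array coloured by group; the axes are component scores, with the percentage of variance each component holds. SCP51 replicate 1 lies alone on component 1 (39.9% of the variance), while component 2 (18.4%) sets SCP51 replicates 2 and 3 apart from the parent and SCP58.

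SCP51 and SCP58 differed in ZBED2, which encodes a zinc finger protein, in the vitamin D-degrading enzyme CYP24A1, in the secreted guidance cue SEMA3A and in the protocadherin PCDH7, all higher in the highly metastatic line. ZBED2 had a mean signal of 580 in SCP51 and 19.9 in SCP58, the latter under the array median. Its log2 difference was 4.86 ± 0.27 (SE, n = 3 per group; limma adjusted p = 0.000245). The differences were 2.93 ± 0.28 for CYP24A1, 2.79 ± 0.28 for SEMA3A and 2.53 ± 0.27 for PCDH7, with adjusted p from 0.00305 to 0.00375. For PCDH7 the parent mean, 8.77 log2 units, lay nearer SCP51 (9.23) than SCP58 (6.70). PCDH7 was lower in SCP58 than in the parent, at -2.08 ± 0.27 (adjusted p = 0.034, a call lost in 8 of 19 alternatives). The antisense transcript CCDC144NL-AS1, dim in SCP58, was higher in SCP51, at 3.87 ± 0.17 (adjusted p = 6.78e-05). Among the genes lower in SCP51 was MARCKS, a membrane-bound substrate of protein kinase C that binds actin, at -2.36 ± 0.15 (adjusted p = 0.000543). VSNL1, a neuronal calcium sensor, stood at -2.30 ± 0.23 (adjusted p = 0.00305). The transporter gene SLC16A14 stood at -2.51 ± 0.35 and the endocytic adaptor EPN3, under the array median in SCP51, at -2.06 ± 0.25. The size of a difference from a dim signal is uncertain: with 32 added before log2 it was 3.56 for ZBED2, 2.34 for CCDC144NL-AS1 and -1.27 for EPN3. With the mean of a gene's probe sets PCDH7 stood at 1.90 and MARCKS at -1.64.

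In all, 555 of 13598 genes were called between SCP51 and SCP58, 201 higher and 354 lower in SCP51, and 197 of them differed at least 2-fold. The excess of lower calls rests on the scaling as deposited, in which the median gene was lower in SCP51 by 0.11 log2 units (a median of -0.11, and -0.05 after quantile normalization). After quantile normalization the split was 319 higher and 302 lower, and after centring on the 75th percentile it was 309 and 297. Every called gene separated the 3 arrays of one line from the 3 of the other. Of all genes, 25.1% did so, against 10% by chance. Array weights gave 1527 calls, the replicate number as a block 210 and only the 6 arrays compared 173. The number of calls was 1189 without SCP51 replicate 1 and 183 without SCP51 replicate 2. It was 326 and 254 without parent replicates 1 and 3, and 344, 137 and 171 without SCP58 replicates 1, 2 and 3. Without SCP51 replicate 3 the split was 108 higher and 481 lower.

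Of the gene lists, 6 were shifted upward and 3 downward in SCP51 relative to SCP58. Of the upward ones, only integrin and matrix adhesion genes and YAP and TEAD targets were also shifted upward in SCP51 against the parent. Wnt and beta-catenin targets, hypoxia and glycolysis genes, neural markers and cholesterol synthesis genes were not (camera adjusted p = 0.27, 0.885, 0.297 and 0.964). Among Wnt and beta-catenin targets, 10 of 13 members were above 0 and 2 were called higher (3 higher and 1 lower when adjusted over the list alone). The adjusted p of that list was 0.00175, and 0.642 with an estimated correlation. One of the called genes was DKK1, a secreted Wnt inhibitor that is itself a Wnt target, at 1.29 ± 0.11 (adjusted p = 0.00305). Of 20 integrin and matrix adhesion genes, 4 were called higher and 1 lower (8 and 1 when adjusted over the list alone). The list had an adjusted p of 0.00101, and 0.642 with an estimated correlation. The laminin chain gene LAMA5 stood at 1.02 ± 0.14 (adjusted p = 0.00891). YAP and TEAD targets had 1 called gene of 17, higher in SCP51 (6 higher and 1 lower when adjusted over the list alone). Here the list adjusted p was 0.00175, and 0.642 with an estimated correlation.

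Hypoxia and glycolysis genes had 18 of 25 members above 0 with 1 called higher (3 when adjusted over the list alone). For this list the adjusted p was 6.48e-05, and 0.834 with an estimated correlation. The called gene was the glucose transporter SLC2A1, at 0.55 ± 0.10 (adjusted p = 0.0232), which stood at -0.23 with the mean of its probe sets. Its call was lost without SCP51 replicate 2 (0.086), parent replicate 3 (0.0524), SCP58 replicate 2 (0.0955) or SCP58 replicate 3 (0.078), and in 7 of 19 alternatives in all. In the list of neural markers 7 of 9 members were above 0 and 2 were called higher, L1CAM and SYT1 (3 when adjusted over the list alone). That list had an adjusted p of 0.00895, and 0.642 with an estimated correlation. L1CAM stood at 0.70, but its 1 other probe set did not share the sign, and with the mean of its probe sets it stood at 0.25 (adjusted p = 0.323). Neither gene kept its call without SCP51 replicates 2 or 3, parent replicates 1 or 3, or SCP58 replicates 2 or 3 (adjusted p from 0.0531 to 0.135), nor did SYT1 without parent replicate 2 (0.052) or SCP58 replicate 1 (0.078). Cholesterol synthesis genes had 11 of 16 members above 0 and none called, over all genes or when adjusted over the list alone. The adjusted p of this list was 0.0296, and 0.834 with an estimated correlation. Its call was lost without SCP51 replicate 2, SCP51 replicate 3 or SCP58 replicate 3 (adjusted p = 0.0683, 0.0705 and 0.0647), and in 4 of 20 alternatives in all.

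Epithelial junction genes lay below 0 in SCP51 in 16 of 18 cases (13 of 18 after either rescaling), with 4 called lower (6 lower and 1 higher when adjusted over the list alone). The list adjusted p was 0.0416, and 0.668 with an estimated correlation. CGN, which encodes the tight junction protein cingulin, stood at -0.66 ± 0.09 (adjusted p = 0.00891). Over its alternatives that p ranged from 0.00685 to 0.0708, the highest with the mean of its probe sets. The desmosomal cadherin gene DSC2 stood at -1.06 ± 0.18, and the epithelial splicing regulator ESRP1, on chromosome 8, at -1.19 ± 0.21 (adjusted p = 0.0205 and 0.0208). Both calls were lost without SCP51 replicate 2 (adjusted p = 0.0753 and 0.0779), SCP58 replicate 2 (0.0905 and 0.0728) or SCP58 replicate 3 (0.0694 and 0.0756), and in 6 and 5 of 19 alternatives in all. The list itself lost its call without SCP51 replicate 3 (0.213), SCP58 replicate 1 (0.0522) or SCP58 replicate 3 (0.0647). It also did so after quantile normalization (0.0655), without an intensity trend (0.0597), with the mean of a gene's probe sets (0.168) and without its chromosome 8 genes (0.0873).

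Of 21 oxidative phosphorylation genes, 2 were called lower, over all genes and when adjusted over the list alone. The list adjusted p was 0.0416, and 0.834 with an estimated correlation. The called genes, UQCRB at -0.76 ± 0.10 (adjusted p = 0.00755) and COX6C at -0.58 ± 0.09 (adjusted p = 0.0156), both lie on chromosome 8. Without its chromosome 8 genes the list had an adjusted p of 0.272. COX6C lost its call without SCP51 replicate 2 (0.0588), SCP58 replicate 2 (0.0762) or SCP58 replicate 3 (0.0591). The list lost it without SCP51 replicate 1 (0.0777), parent replicate 1 (0.0574), parent replicate 2 (0.0551), SCP58 replicate 1 (0.0871) or SCP58 replicate 3 (0.0935). Its adjusted p was 0.0629 with a stricter filter, 0.0779 without an intensity trend, 0.203 with array weights, 0.184 with the mean of a gene's probe sets and 0.0589 with only the 6 arrays compared, so the call was lost in 11 of 20 alternatives. Ribosomal protein genes lay below 0 in 19 of 19 cases (17 after quantile normalization and 16 after centring) with none called, over all genes or when adjusted over the list alone. Their median was -0.15, or -0.05 relative to the median of all genes. The list adjusted p was 0.00707, 0.834 with an estimated correlation and 0.0939 without an intensity trend.

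TGF-beta targets were not shifted as a list between SCP51 and SCP58 (adjusted p = 0.0649), with a median of -0.02, a median of 0.05 after quantile normalization and a mean of 0.07, while the test pointed upward. Leaving out its 1 chromosome 8 gene, an alternative added after seeing the data, the list was shifted upward (camera adjusted p = 0.0364). Of its 17 members 3 were called higher (6 higher and 3 lower when adjusted over the list alone). Of 22 genes of MAPK and EGFR feedback, 1 was called higher and 2 lower (2 and 2 when adjusted over the list alone). The list was not shifted (adjusted p = 0.65), with a median of -0.13 while the test pointed upward. The higher MAPK gene was DUSP6, an ERK phosphatase, at 1.01 ± 0.14 (adjusted p = 0.00891).

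By chromosome, a property looked at after the values were seen, 73 of the 354 genes lower in SCP51 than in SCP58 lay on chromosome 8. That is 20.6% of them, while the chromosome held 3.47% of the genes tested, and 8 of its 472 genes were higher. A stretch of 161 measured neighbours from YTHDF3 to SQLE, located with every second gene, held 50 called genes, all lower. The 80 genes of the stretch that had not been used to locate it had a median log2 difference of -0.55 relative to all genes.

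**Figure D2:**
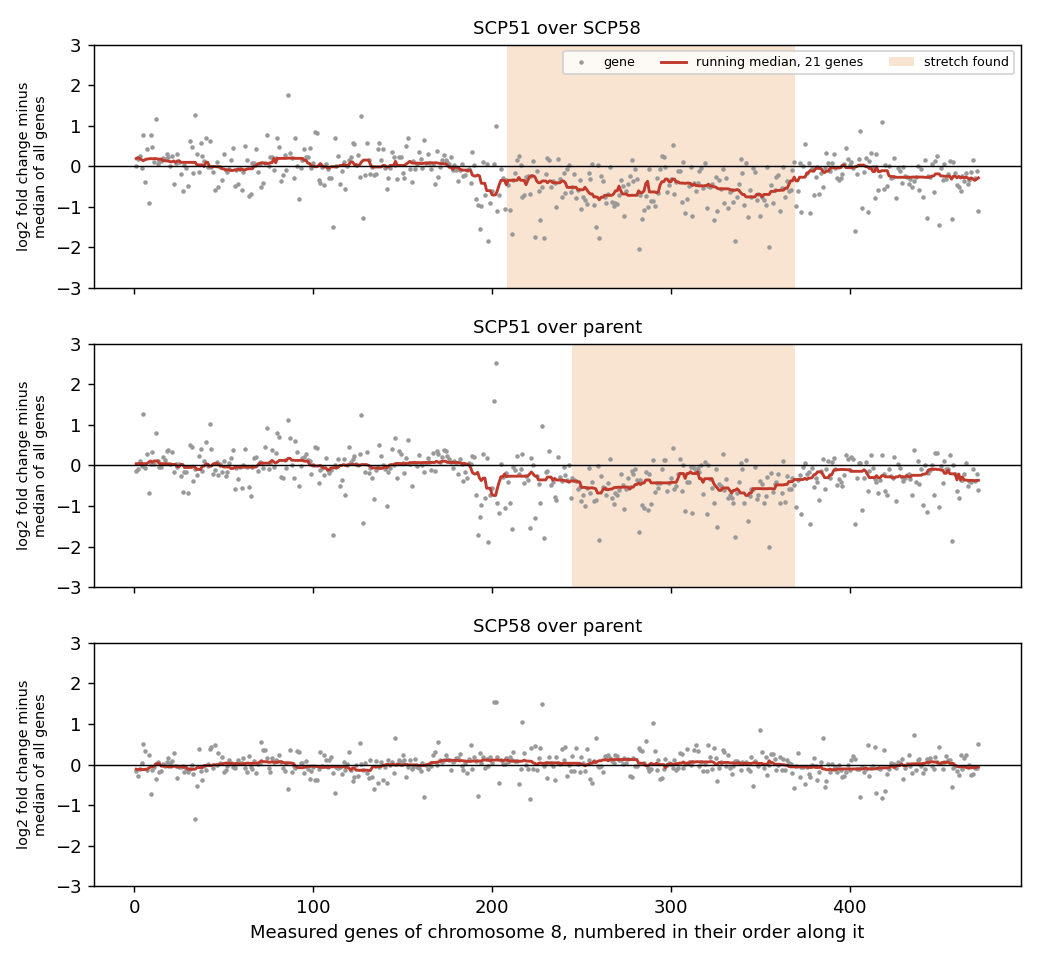
Log2 fold change of each measured gene of chromosome 8 minus the median of all genes, in the order of the genes along the chromosome, for the 3 comparisons; grey points are genes, the red line is the running median over 21 genes, and shading marks the stretches located in a comparison. The shaded stretch lies below 0 over 161 genes for SCP51 over SCP58 and over 125 genes for SCP51 over the parent, and no stretch was located for SCP58 over the parent.

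Set against the parent, SCP51 had higher levels of the homeobox transcription factor HOXB8, CYP24A1, the transcription factor GLIS3 and SEMA3A. It had lower levels of VSNL1, the hyaluronan synthase HAS3, the calcium-binding protein S100A14 and MARCKS. HOXB8 rose by 4.49 ± 0.31 log2 units (SE, n = 3 per group; limma adjusted p = 0.000348). CYP24A1 rose by 3.33 ± 0.28, GLIS3 by 2.95 ± 0.25 and SEMA3A by 2.88 ± 0.28, with adjusted p from 0.000852 to 0.00228. In the parent, HOXB8, CYP24A1 and GLIS3 lay under the array median. The log2 differences were -3.62 ± 0.23 for VSNL1, -2.71 ± 0.18 for S100A14 and -2.60 ± 0.15 for MARCKS (each with an adjusted p of 0.000348), and -2.78 ± 0.23 for HAS3 (adjusted p = 0.000852). The 1 other probe set of HAS3 did not share its sign, and with the mean of its probe sets HAS3 stood at -1.26 and GLIS3 at 1.97. With 32 added before log2, the dim parent signals gave 3.46 for HOXB8, 2.48 for CYP24A1 and 1.82 for GLIS3.

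Between SCP51 and the parent, 402 genes were called, 187 higher and 215 lower, of which 164 changed at least 2-fold. Quantile normalization gave 247 higher and 169 lower, and centring on the 75th percentile 248 and 183. Of all genes, 28.1% separated the groups, against 10% by chance. There were 1356 calls with array weights, 167 with the replicate number as a block and 184 with only the 6 arrays compared. Calls numbered 724 without SCP51 replicate 1, 158 without SCP51 replicate 2, and 135, 153 and 122 without parent replicates 1, 2 and 3. Without SCP58 replicate 2, which enters through the shared spread, there were 263. Without SCP51 replicate 3 the split was 110 higher and 366 lower.

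YAP and TEAD targets had 14 of 17 members above 0 in SCP51 relative to the parent, with 4 called higher and none lower (8 higher when adjusted over the list alone). The list adjusted p was 1.2e-07, the smallest in this comparison, and 0.413 with an estimated correlation. Among them CRIM1, a transmembrane binder of bone morphogenetic proteins, rose by 1.31 ± 0.15 (adjusted p = 0.00389). Integrin and matrix adhesion genes had 4 called higher and 1 lower of 20 (6 and 1 when adjusted over the list alone). Their list adjusted p was 0.000665, and 0.864 with an estimated correlation. The integrin subunit gene ITGB8, dim in the parent, stood at 2.61 ± 0.39, at 1.87 with 32 added before log2 and at 1.33 with the mean of its probe sets (adjusted p = 0.0114, 0.0121 and 0.0566, and 0.0503 without SCP51 replicate 2). LAMA5 was 1.88-fold higher (adjusted p = 0.0143, and 0.0666, 0.0631 and 0.0629 without parent replicates 1, 2 and 3). TGF-beta targets were not shifted (list adjusted p = 0.274), with a median of -0.04, a median of 0.04 after quantile normalization and a mean of 0.11. Even so 4 of 17 were called higher and 1 lower (4 and 2 when adjusted over the list alone). They include the receptor gene TGFBR2 at 1.04 ± 0.14 (adjusted p = 0.00717; 0.61 with the mean of its probe sets) and the pathway inhibitor SMAD7, dim in the parent, at 1.17 ± 0.16 (adjusted p = 0.00804; 0.60 with 32 added before log2).

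Of 17 genes tied to colorectal cancer metastasis, 3 were called higher in SCP51 than in the parent (4 higher and 1 lower when adjusted over the list alone). The list adjusted p was 0.0454, and 0.864 with an estimated correlation. TIAM1, an activator of the GTPase Rac, was 2.83-fold higher (adjusted p = 0.0117, ranging from 0.00848 to 0.0658 over its alternatives), with a log2 difference of 0.82 with the mean of its probe sets. It was nearly as high in SCP58, with log2 signals of 9.59, 9.09 and 9.67, against 9.81, 9.56 and 9.39 in SCP51. Its higher signal was thus not particular to SCP51, although TIAM1 was not called between SCP58 and the parent. The list lost its call without SCP51 replicate 1 (0.17) or parent replicate 1 (0.177), with no filter (0.053) or a stricter one (0.0565), after quantile normalization (0.0629), without an intensity trend (0.0561), with array weights (0.128) and with the mean of a gene's probe sets (0.111), and in 10 of 20 alternatives in all. DNA replication genes lay below 0 in 23 of 24 cases with 1 called, also when adjusted over the list alone. This list had an adjusted p of 0.0406, and 0.864 with an estimated correlation. Its call was lost without SCP51 replicate 1 (0.217), SCP51 replicate 3 (0.0921) or parent replicate 1 (0.297). It was also lost with a stricter filter (0.052), without an intensity trend (0.0561), with array weights (0.234) and with the mean of a gene's probe sets (0.0581), and in 9 of 20 alternatives in all. Ribosomal protein genes lay below 0 in 19 of 19 cases (16 of 19 after either rescaling) with none called, over all genes or when adjusted over the list alone. Here the list adjusted p was 0.00439, 0.864 with an estimated correlation and 0.0841 without an intensity trend. In all, 5 lists were shifted between SCP51 and the parent, against 3 without parent replicate 1 and 9 without parent replicate 2.

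**Figure D3:**
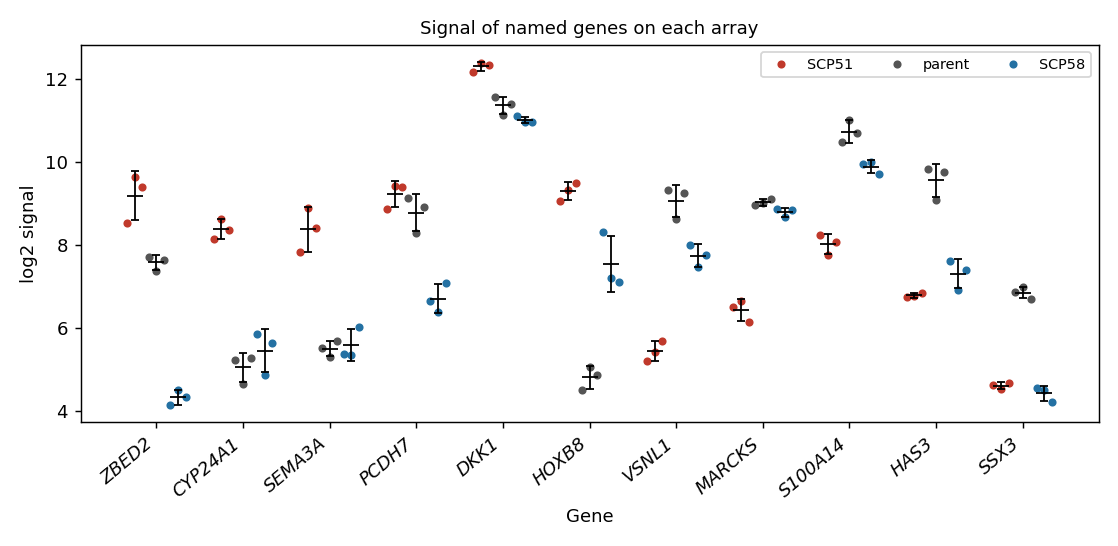
Log2 signal of 11 named genes on each of the 9 arrays, with 1 point per array, coloured by group; the horizontal bar is the group mean and the whisker its SD (n = 3). ZBED2 steps down from SCP51 to the parent to SCP58, with means of 9.18, 7.57 and 4.32, and SSX3 is lower in both single cell-derived lines than in the parent.

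In the main fit few genes were called between SCP58 and the parent. That count depends on the model: it was 1351 with array weights, 37 with only the 6 arrays compared and 6 with the replicate number as a block. SSX3 and SSX1, cancer-testis antigen genes of similar sequence, were lower in SCP58, at -2.43 ± 0.14 and -2.16 ± 0.16 (SE, n = 3 per group; limma adjusted p = 0.000632 and 0.00284). Both were dim in SCP58, and without a parent array neither passed the filter. With 32 added before log2, SSX1 stood at -1.43 and ZBED2, described next, at -2.10. ZBED2 stood at -3.26 ± 0.27, and PALS1, a polarity scaffold at cell junctions, rose by 1.81 ± 0.14 (each with an adjusted p of 0.00322). HOXB3 rose by 1.51 ± 0.14 (adjusted p = 0.00491), and stood at 0.77 with the mean of its probe sets (adjusted p = 0.274). A total of 19 genes were called, 9 higher and 10 lower, with 12 and 11 after quantile normalization and 14 and 10 after centring. Of all genes, 17.0% separated the groups, against 10% by chance. Without parent replicate 1, limma called 0 genes, and ZBED2, PALS1 and HOXB3 each had an adjusted p of 0.0526. In that fit 658 genes had an unadjusted p under 0.05, against 1169 with all arrays. The 658 lie near the share of 0.05 that chance alone would give. That share cannot show that SCP58 and the parent are alike, since the shared spread also holds SCP51 replicate 1, which stood apart. Calls numbered 75 without SCP51 replicate 1, 11 and 7 without parent replicates 2 and 3, and 8 without SCP58 replicate 3.

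Gene lists were shifted between SCP58 and the parent with few single genes called. All 25 hypoxia and glycolysis genes lay below 0 (24 after quantile normalization, where TPI1 lay above), with a median of -0.47 and none called, over all genes or when adjusted over the list alone. As a list they had an adjusted p of 9.92e-09, and 0.67 with an estimated correlation. Its brightest members, GAPDH and LDHA, stood at -0.01 ± 0.04 and -0.17 ± 0.06. Picked after their values were seen, the kinase gene PDK1 stood at -0.96 ± 0.25 and VEGFA at -0.59 ± 0.19. All 17 p53 targets lay above 0, also after either rescaling, with a median of 0.28 and none called (2 when adjusted over the list alone). Their list adjusted p was 4.89e-06, and 0.67 with an estimated correlation. CDKN1A, the brightest member, stood at 0.20 ± 0.14, and, picked after their values were seen, FAS stood at 0.65 ± 0.12 and TP53I3 at 0.82 ± 0.20. YAP and TEAD targets were above 0 in 13 of 17 cases with 1 called higher (4 higher and 1 lower when adjusted over the list alone). This list had an adjusted p of 0.00674, and 0.67 with an estimated correlation.

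The 5 other lists shifted between SCP58 and the parent each lost the call in at least 1 fit that left out an array. None of their members was called; when adjusted over the list alone, Wnt and beta-catenin targets had 1 higher and 3 lower and the rest none. Epithelial junction genes were shifted upward (adjusted p = 0.037; 0.102 without parent replicate 1, 0.0824 without SCP58 replicate 1 and 0.0938 without SCP58 replicate 3). Cholesterol synthesis genes were shifted downward (0.00144; 0.261 without parent replicate 2), as were DNA replication genes (0.0114; 0.202 without parent replicate 1, 0.0824 without SCP58 replicate 1 and 0.0748 without SCP58 replicate 2). Heat shock genes were too (0.0288; 0.0778 without parent replicate 1, 0.195 without SCP58 replicate 1 and 0.0507 without SCP58 replicate 2). So were Wnt and beta-catenin targets (0.0374; 0.0566 without SCP51 replicate 2, 0.0695 without parent replicate 1, 0.0824 without SCP58 replicate 1 and 0.0583 without SCP58 replicate 2). The Wnt list also lost its call without its chromosome 8 genes (0.0734), with no filter (0.206) or a stricter one (0.0542), without an intensity trend (0.0577) and with the mean of a gene's probe sets (0.113). Of 20 alternatives chosen before the data were examined, 9 lost the call for the Wnt list, 6 for epithelial junction, 6 for heat shock, 4 for DNA replication and 3 for cholesterol synthesis. With an estimated correlation the adjusted p was 0.917 for DNA replication and 0.67 for each of the others. In all, 8 lists were shifted between SCP58 and the parent, against 4 without SCP58 replicate 1.

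**Figure D4:**
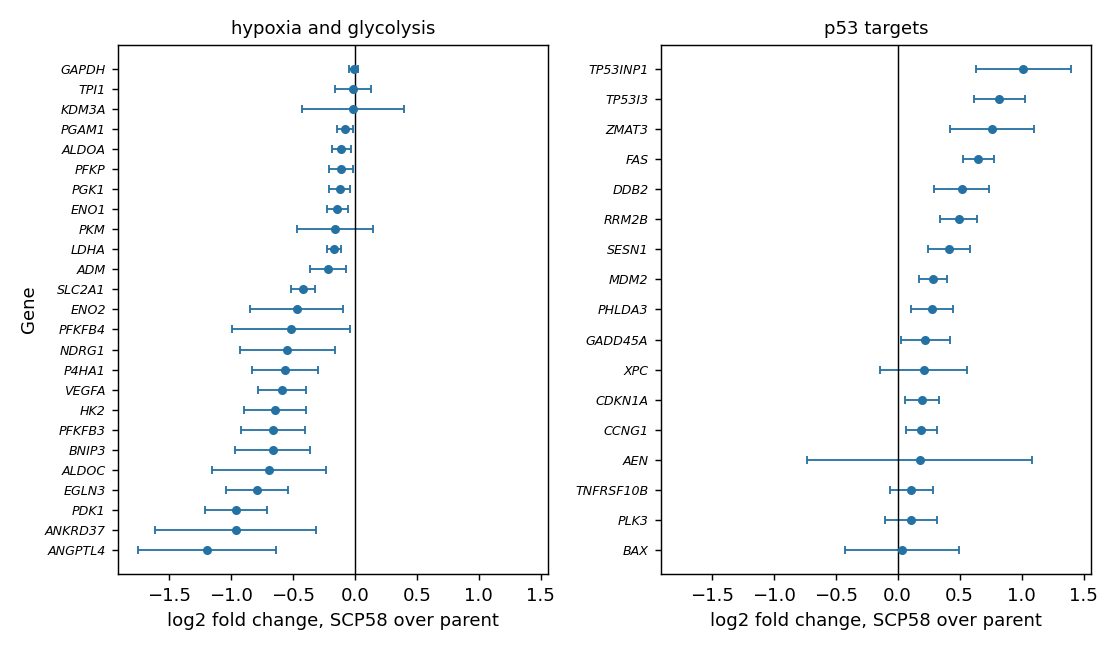
Log2 fold change of SCP58 over the parent for each measured gene of the hypoxia and glycolysis list and of the p53 target list; points are estimates from 3 arrays per group and whiskers their SE. All 25 genes of the first list lie below 0 (24 after quantile normalization) and all 17 of the second above it, and none was called.

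Both single cell-derived lines differed from the parent in 14 genes, 13 of them in the same direction, named here after their values were seen. Higher in both were HOXB3, HOXB8, PALS1, INPP4B, EFNA5, CAV2 and ZDHHC4, and lower in both were CAPN6, HAS3, SSX1, SSX3, NETO2 and BAMBI. PALS1, for example, rose by 2.03 ± 0.14 in SCP51 (adjusted p = 0.000358), beside its rise in SCP58. The phosphatase gene INPP4B rose by 2.29 ± 0.15 in SCP51 and by 1.41 ± 0.15 in SCP58 (adjusted p = 0.000348 and 0.00884). Its SCP58 call was lost without parent replicate 1 (0.0818), parent replicate 2 (0.0522) or SCP58 replicate 3 (0.066). Calls in SCP58 were lost in 11 of 19 alternatives for ZDHHC4, 10 for EFNA5, 5 each for CAV2, NETO2 and BAMBI, 4 each for HOXB8 and INPP4B, 3 each for HOXB3 and HAS3 and 1 for PALS1, and in 1 of 15 for CAPN6. In SCP51 they were lost in 7 for ZDHHC4, 6 for CAV2 and 1 each for HOXB3, EFNA5 and BAMBI, and in 1 of 15 for CAPN6. SSX1 and SSX3 kept both calls in the 16 alternatives that gave a value. CAPN6 stood at -0.21 in SCP51 and -0.39 in SCP58 with no filter (adjusted p = 0.486 and 0.626), and EFNA5 at 0.08 and 0.11 without SCP51 replicate 3 (0.853 and 0.986), in each case because another probe set then stood for the gene. CAV2 stood at 0.33 and 0.62 with the mean of its probe sets (0.243 and 0.23). It lost its SCP51 call without SCP51 replicate 2 or parent replicates 1 or 3 (0.0545 to 0.0853) and its SCP58 call without parent replicates 1 or 3 or SCP58 replicate 3 (0.066 to 0.0917). ZDHHC4 lost its SCP58 call without any 1 array but SCP51 replicate 1 (0.0607 to 0.223) and its SCP51 call without SCP51 replicates 2 or 3 or any parent array (0.0512 to 0.11). Without a parent array the SCP58 calls of EFNA5, NETO2 and HOXB8 were lost each time (0.0522 to 0.126), and those of HAS3 and BAMBI without parent replicates 1 or 3 (0.0658 to 0.0917). SCP58 calls were also lost without SCP58 replicate 1 (EFNA5, 0.0865), 2 (NETO2 and BAMBI, 0.0565 and 0.0568) or 3 (EFNA5, HAS3 and BAMBI, 0.14, 0.066 and 0.066). Independent lists of these lengths would share 0.124 higher and 0.158 lower genes. In 100 simulations of unchanged groups that shared a parent group, 0 shared calls was the highest count. Unchanged groups give hardly any calls at an adjusted p under 0.05, so a count of 0 was built in. That count cannot show whether the 13 shared calls exceed what the shared parent arrays bring. Across genes, the covariance of the log2 fold changes was 0.0532, against a mean of 0.0368 and a highest of 0.0447 in the simulation, a difference of 0.0164, while the correlation was 0.397 against 0.502. The simulation used the same parent arrays for both comparisons, with a spread pooled over the groups, so their independent error was already in its mean. From the spread of the parent arrays alone the covariance would be 0.0239, a difference of 0.0292. An error common to the parent arrays was not simulated and may make up part of the excess. The 3 parent arrays were too few to split between the comparisons. The number of genes shared in direction was 32 without SCP51 replicate 1, 0, 8 and 5 without parent replicates 1, 2 and 3, and 7 without SCP58 replicate 3.

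ZBED2 was the 1 gene called in opposite directions, at 1.61 ± 0.27 in SCP51 against the parent (adjusted p = 0.0178) and at -3.26 in SCP58. The SCP51 part lost its call without SCP51 replicate 2 (0.056) or parent replicates 1, 2 or 3 (0.0638, 0.0794 and 0.0716), and the SCP58 part without parent replicate 1 (0.0526). Without SCP51 replicate 1, 2 genes were called in opposite directions. Among the 201 genes higher in SCP51 than in SCP58, the parent mean lay between the lines for 134 and nearer SCP58 for 154. Among the 354 lower ones, it lay between for 293 and nearer SCP58 for 285.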

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

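No test was added for the result given here after it was seen. ZBED2 is listed because its change against the parent had opposite signs in the lines. The effect in SCP51 minus that in SCP58 was 4.86 log2 units, which is the SCP51 against SCP58 contrast of the same model (limma adjusted p = 0.000245, with 3 of 3 SCP51 arrays above all SCP58 arrays). Over its alternatives the adjusted p of that contrast ranged from 1.89e-06 to 0.00832.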

How the results depend on the processing

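Leaving chromosome 8 genes out of the lists was chosen after seeing the data, and the other alternatives before. Under those, the 84 named gene differences taken by the rule gave 1545 values. Of these, 1193 kept their direction and call, 1 reversed and the rest kept the direction without the call. The reversed one was SLC2A1 between SCP51 and SCP58, at -0.23 with the mean of its probe sets. Of the named differences, 29 held under every alternative that gave a value; genes near the filter gave none when an array was left out. The 22 list calls gave 440 values, of which 357 held and 83 lost the call. With an estimated correlation, camera shifted 0, 0 and 0 lists in the comparisons of SCP51 with SCP58, SCP51 with the parent and SCP58 with the parent, with 1, 1 and 0 at an unadjusted p under 0.05. For SCP51 against the parent, 3 lists were shifted with the filter at the 65th percentile, with array weights and with the mean of probe sets, and 2 without an intensity trend. Without chromosome 8 genes 8, 5 and 7 lists were shifted. Between SCP51 and SCP58 the epithelial junction and oxidative phosphorylation lists then lost the call, and TGF-beta targets gained it. In the same order, array weights raised the calls to 1527, 1356 and 1351, the shared calls to 230 and the genes called in opposite directions to 62. Testing every probe set by itself gave 976 calls between SCP51 and SCP58, 39 between SCP58 and the parent and 30 shared. With only the 6 arrays compared there were 173, 184 and 37 calls and 0 genes called in opposite directions. The causes were not tested. By their construction, a 2-fold limit left 197 and 164 calls for the SCP51 comparisons, and an adjusted p under 0.01 left 124, 102 and 12, with 8 shared and 0 in opposite directions. Leaving out single arrays gave 137 to 1189, 122 to 724 and 0 to 75 calls, 0 to 32 shared calls, 0 to 2 genes in opposite directions, and 6 to 13, 3 to 9 and 4 to 9 shifted lists. Genes near the array median have little signal over background, and without detection calls their differences are the least certain.

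With the replicate number as a block, there were 210, 167 and 6 calls, 5 shared calls and 3 shifted lists for SCP51 against the parent. The numbers did not pair the arrays in general. Of 9 same-numbered pairs across groups, 1 had deviations from the group means that correlated above 0.1. That pair was parent replicate 2 and SCP58 replicate 2, each of which correlated best with the other. The range over the 9 pairs was -0.22 to 0.13, against -0.12 to 0.12 for other numbers. Counting arrays that correlated best with their own number in both other groups gave 0.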

Other observations

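The families and the chromosome were looked at after their values had been seen, as were all the tests below except the counts of other splits.

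Of 19 measured HOX genes, transcription factors that set position along the body axis, 4 were called higher in SCP51 than in the parent, all of the HOXB cluster, and 10 lay below 0. HOXB4 rose by 1.24 ± 0.14 log2 units (SE, n = 3 per group; limma adjusted p = 0.00385) and HOXB6 by 1.59 ± 0.22 (adjusted p = 0.00977), beside HOXB3 at 1.99 ± 0.14 and HOXB8. HOXB4 stood at 0.80 with 32 added before log2, and HOXB3 and HOXB6 at 0.72 and 0.81 with the mean of their probe sets (for HOXB3 with an adjusted p of 0.0818). In SCP58, 2 HOX genes were called higher than in the parent, HOXB3 and HOXB8, the latter not without parent replicates 1, 2 or 3 (0.126, 0.0542 and 0.0876). Of 23 measured collagens, 4 were called higher in SCP51 than in the parent and 3 higher than in SCP58, while 12 lay below 0 in each comparison (11 after either rescaling). Neither family was tested for enrichment, so these are statements about single genes. COL6A3 rose by 2.22 ± 0.18 against the parent (adjusted p = 0.000676) and by 1.61 ± 0.18 against SCP58 (adjusted p = 0.0041), or by 1.01 and 0.81 with 32 added before log2. COL6A1 rose by 0.86 ± 0.10 in both comparisons (adjusted p = 0.00419 and 0.0052; 0.787 and 0.526 with the mean of its probe sets). Without an SCP51 array COL6A3 did not pass the filter.

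COL6A3 is also 1 of 5 measured genes on the list of fibroblast markers, which was not shifted against SCP58 or the parent (adjusted p = 0.209 and 0.454). FBLN1 was called higher as well, at 0.72 ± 0.12 against SCP58 and 0.64 ± 0.12 against the parent (adjusted p = 0.0196 and 0.0325). Over the alternatives for FBLN1 these differences went down to 0.11 and 0.02. Its calls were lost without SCP51 replicates 1, 2 or 3 (adjusted p from 0.568 to 0.69 and from 0.841 to 0.946) and without SCP58 replicates 2 or 3 (0.0901 and 0.0652, and 0.058 and 0.0601). The call against the parent was also lost without parent replicates 1, 2 or 3 (0.121, 0.113 and 0.0914). The filter and the choice of probe set were repeated in each fit. With the probe set unchanged, the differences without each SCP51 array would average to the full one, which they did not. Another probe set thus stood for FBLN1 in at least some of those fits, so these losses need not mean dependence on single SCP51 arrays. Against SCP58, COL1A1, DCN and PDGFRA stood at -0.15 ± 0.14, -0.36 ± 0.22 and -0.48 ± 0.18, none called.

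Splits of the 6 arrays of a comparison into other groups of 3 are too few, at 10, for a share under 0.05. The real grouping gave 555, 402 and 19 called genes for SCP51 against SCP58, SCP51 against the parent and SCP58 against the parent, and the highest other split 11, 6 and 1; in each case 1 of the 10 splits, the real one, gave as many. For gene lists the real groupings gave 9, 5 and 8 shifted lists and the highest others 6, 8 and 10, so that 1, 5 and 4 of the 10 splits reached the real number. Of 100 splits of the 9 arrays into 3 groups, 1, the real one, gave as many as 1 gene called in opposite directions against the parent, with 0 at most in the others. That is a share under 0.05, but it rests on 1 gene, and the count was 0 without SCP51 replicate 2 or any 1 of the parent arrays, so little weight can be put on it. For the 13 genes changed in the same direction in both lines, 2 of 100 splits gave as many. This share under 0.05 weighs only against all 9 arrays being alike, and splits that mix differing lines widen the spread and so lower the calls. It does not exclude an error that the parent arrays share, and without parent replicate 1 the count was 0. The highest other gave 159, and that split put the 3 SCP51 arrays in the place of the parent, which shows that SCP51 stands apart from the other 6 arrays. The next highest gave 12 and 11, close to 13.

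The stretch of chromosome 8 with lower signal in SCP51 was weighed against a pair of technical sources. Without SCP51 replicate 1 the median of its 80 genes that had not been used to locate it was -0.42 relative to all genes, and 0 of 10000 random lists matched on mean signal had a median as low as the -0.55 seen with all arrays, which argues against that array and against a bias tied to signal. Of these genes, 91.3% lay below the median of all genes, as a lower DNA copy number of the region in SCP51 would need. A lower copy number in SCP51 is therefore a candidate explanation, as a hypothesis, since no DNA was measured and regulation of neighbouring genes stays untested. A stretch of 21 neighbours at the end of chromosome X, up to VCX2, lay higher in SCP51 than in SCP58, with 8 called higher and a median of 0.82 over the 10 genes not used to locate it.

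SCP51 replicate 1 stood apart from the other 8 arrays. Degraded RNA would raise the ratio of 3' to 5' signal, but for GAPDH it was 0.761, against 0.894 to 0.957 on the other arrays, and for beta-actin 1.08, against 0.938 to 1.16. A sample of SCP58 under an SCP51 label would sit at SCP58 over genes that separate the lines. On a scale from SCP58 at 0 to the other SCP51 arrays at 1, its lowest of 3 median positions was 0.611. For SCP58 arrays left out in turn the position was 0.196 at most. Across all genes, however, its highest correlation was with SCP58 replicate 3, at 0.911, against 0.903 and 0.909 with SCP51 replicates 2 and 3. The positions speak only against a sample of SCP58 alone, and other causes of the intermediate position of this array were not tested. A fault of hybridization stays open: the SD of its 45 spike-in probe sets around the other arrays was 0.284 log2 units, above 0.0816 to 0.255 on the other arrays but not by a wide margin, so it cannot be told apart from a different state of that culture, which was not tested.

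The 13 genes changed in the same direction in both lines may mark a property of the parent sample. Against independent error of the parent arrays, genes were picked without 1 parent array at an unadjusted p under 0.001 in both comparisons; the array left out had a median position of 1.11, 0.801 and 0.863 for parent replicates 1, 2 and 3, from the 6 other arrays at 0 to the remaining parent arrays at 1. Over all genes picked, the array left out lay above 0 for 20 of 20, 27 of 29 and 26 of 29. The lowest was DDB2, at -0.142 for parent replicate 2. Of the 13 genes, 11 were picked each time, with positions from 0.747 to 1.35 (CAPN6, SSX1 and SSX3 needed all 3 parent arrays to pass the filter). The 13 had been called with all 3 parent arrays, so that range was largely set by the choice of genes and does not count against such error. For single genes it stays open, also for CAV2 and ZDHHC4, which were not picked each time. Whichever parent array was left out, at least 87.2% of the log2 fold change of each of the 13 genes was left in both lines. A gene driven by 1 parent array could hardly be among genes called with all 3, so this cannot speak against 1 deviating array. No shared call passed the adjusted limit without parent replicate 1 (PALS1 in SCP58 stood at 1.75 with an adjusted p of 0.0526). A difference in culture or processing of the parent cannot be told apart from a difference between a mixed population and lines grown from 1 cell, since both would give the same 13 genes and the parent is 1 group of arrays.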
